A study of Homo sapiens and Mus musculus with 9 samples.

How the data were processed

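The series holds 9 samples in 9 groups, with 1 library per group and no replicate. Of these, 4 are ribosome profiling (Ribo-seq) libraries of the human embryonic kidney line HEK293. They are a control, a starvation library and a pair of starvation libraries transfected with a trans-RNA against ATF4, called trans1 and trans2 here. A pair of HEK293 small RNA libraries was made from total and from capped small RNA. The remaining 3 libraries are RNA-seq of mouse liver after feeding, after fasting, and after fasting with a trans-RNA against ATF4. The labels give trans1 and trans2 the same treatment, so whether they are repeats or different RNAs is not stated, and they were kept as separate groups.

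The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 2.8, Bowtie 1.2.3 and STAR 2.7.10a without a role or order, and the build GRCm39 for the Ribo-seq and liver samples. The offset applied to the footprint positions is not given in the sources used here. Per the file headers and values, the units were as follows. The deposited density tables hold a signal per nucleotide around start and stop codons, relative to the mean of the same transcript. In the deposited open reading frame lists, read totals are expected counts from the frame caller PRICE, each with a p-value and a score for start and range. The authors' fold tables hold 1 log2 fold change per open reading frame under human transcript IDs, and their scaling is unknown. The deposited peak lists hold counts of reads at peak positions, with a lowest value of 4, and a distance from the start codon, the other value per peak. The deposited liver tables hold RPKM and TPM per transcript, and the authors' TPM is the RPKM scaled to a common sum. All gene IDs in the open reading frame lists of the HEK293 libraries are mouse IDs, and the genome those reads were placed on was not settled here.

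The design fixed before the data were examined assumed a normalised value per gene. No such table was used for Ribo-seq, because each density value is a whole multiple of a step that belongs to 1 transcript and library. The step equals coding length divided by the reads of that transcript, so read numbers were recovered from steps in at least 2 libraries with reads at 8 or more positions. The recovered lengths were multiples of 3 by construction, with a median coding length of 1161 nt. A recovered length can be a divisor of the true one, which lowers a transcript's reads in each library alike. In 200 control transcripts just long enough for separate windows, the recovered total was 1.34 times the coding reads in the windows, where an even spread gives 1.22. Whether the total takes in reads outside the coding region was not settled, and it is called reads per transcript. This gave 9431 of 16984 transcripts, of which 9417 were listed in all 4 libraries. Depth after recovery was 10408120 reads in control, 9171014 in starvation, 5982735 in trans1 and 7309758 in trans2. Reads were divided by the library's recovered reads and scaled to 1000000 (CPM).

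The liver RPKM were turned into reads in the same way, from ratios of whole numbers, for 17690 of 20100 transcripts, with 10755276 reads for fed, 10134698 for fasting and 12003218 for fasting with trans1. On simulated tables with known reads, all ratios of 1494 transcripts came back within rounding, and so did the depth ratios of 16574 simulated liver transcripts. These simulated values carried full precision.

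The main measure was log2((b + 1)/(a + 1)) on CPM or RPKM, for transcripts with a value of at least 1 in at least 1 of the libraries compared. Counts of transcripts at least 2-fold higher or lower are a rule of size. With 1 library per group no test of a difference was run and no p-value was computed. On simulated counts, a 3-fold change of 200 transcripts was called for 197 in starvation against control, 196 in trans1 and 195 in trans2, with at most 2 unchanged transcripts called. In liver, 63.7% of tested 3-fold changes were called for fasting against fed and 65.9% for trans1 against fasting, or 39.5% and 44.5% of all 200 changed, with 22 and 13 unchanged transcripts called. Intervals are exact 95% binomial (Clopper-Pearson) intervals for shares and for ratios of reads. They cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of mean densities come from 1000 bootstrap draws over transcripts and say nothing of replicate error.

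Gene symbols for human transcripts came from the peak lists, which pair 5745 transcript IDs with symbols. These named 2694 of the 9431 transcripts. The rule for named genes was ATF4 first, then the 10 highest and 10 lowest log2 ratios among genes with at least 10 CPM, leaving out histones and pseudogenes, plus members of fixed lists. No table here pairs a transcript with ATF4, so ATF4 was not analysed here by name. No table pairs mouse transcripts with symbols, so the 23 mouse gene lists were not used and at most 4 mouse IDs are printed per comparison. The transcript with the largest gain in trans1 has no symbol and was singled out after its values were seen.

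Of the 16 human lists, the number of members measured was 38 for ribosomal proteins, 11 for immediate early genes, 10 for cell cycle genes, 9 for nuclear respiratory chain genes and 8 for cytosolic aminoacyl-tRNA synthetases. It was 7 each for ATF4 and integrated stress response genes and for lysosome and autophagy genes, and 6 each for cholesterol synthesis genes, NRF2 targets and mRNAs with regulatory upstream frames. It was 5 each for chaperones, endoplasmic reticulum unfolded protein response genes and p53 targets, 3 each for glycolysis and for translation factors of TOP mRNAs, and 2 for interferon-stimulated genes, too few for a median. A list's median was placed among 10000 random lists of named transcripts of the same size, matched on mean expression in 10 bins. A list outside the central 95% is said to stand apart in these libraries. Of 40 simulated lists of 20 members with no shift, 1 lay below that range and none above. Of 40 with a shift of 0.5, 37 lay above it.

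Both trans-RNA ratios share the starvation library, which enters the starvation ratio with opposite sign, and both liver ratios share the fasting library. Overlaps and covariances were therefore set beside 200 simulations in which the libraries differ by counting noise alone. Peaks were called shared when they lie on 1 transcript within 10 nt. Neighbouring small RNA genes were taken from the RefSeq gene table of GRCh38.p14. Alternatives fixed beforehand changed the pseudocount, the filter, the fold threshold, the centring, the matching of lists and, for Ribo-seq, the use of the authors' fold values. Added after the data were seen were reads of the start or stop window alone, reads at 8 or more positions, removal of each transcript's highest position, liver CPM, at least 50 liver reads and, for the return towards fed, a filter on fed and fasting alone. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.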

Results

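Ribosome footprints were measured in HEK293 cells under control conditions, under starvation, and under starvation after transfection of a trans-RNA directed at the main open reading frame of ATF4, a transcription factor of the integrated stress response. There were 4 such libraries, 1 per group, with 10408120 footprints recovered for control, 9171014 for starvation, 5982735 for trans1 and 7309758 for trans2. Small RNA from the same line was profiled as 1 total and 1 cap library, seen here as peaks on mRNAs. Liver RNA of fed, fasted and fasted trans-RNA-treated mice was profiled with 10755276, 10134698 and 12003218 recovered reads. No group had a replicate, so intervals in brackets are exact 95% intervals of counting error unless named as ranges of random draws, and differences between groups were not tested against biological variation.

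The first comparison asks what starvation does to ribosome footprints in these cells. The series holds no RNA-seq of HEK293, so changes in mRNA level and in translation cannot be told apart in any footprint comparison. Footprints on ribosomal protein mRNAs and on mRNAs of cholesterol synthesis were lower after starvation, whereas immediate early genes were higher. Of 38 ribosomal protein mRNAs, 33 were below 0, with a median log2 ratio of -0.32 at percentile 0.16 of matched random lists. RPL12 was at -1.12, RPS19 at -1.11 and RPL27A at -1.0. All 6 cholesterol mRNAs were lower, with a median of -0.93, beyond every one of the 10000 random lists. They include HSD17B7 at -1.38, DHCR7, the last enzyme of the pathway, at -1.23 and SQLE, which makes squalene epoxide, at -0.87.

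Cytosolic chaperones were lower too, 5 of 5, with a median of -0.66 at percentile 0.385. The inducible HSP70 gene HSPA1B was at -1.74 (-1.92 to -1.61), HSPA4 at -0.94 and the constitutive HSPA8 at -0.66. Among 11 immediate early mRNAs the median was 0.38 at percentile 99.6, but 0.25 and inside its range with the stop window alone. IER5 was at 0.94 and FOSL1 at 0.79, but DUSP1, a phosphatase, was at -0.65 and KLF4 at -0.66.

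Genes of the ATF4 and integrated stress response list did not stand apart from random lists under starvation, with a median of 0.08 over 7 members, or -0.33 with the start window alone and -0.18 with the stop window alone. CEBPB, a transcription factor of this response, was at 0.80 (0.59 to 1.06) and ALDH18A1, a proline synthesis enzyme, at -0.58. The endoplasmic reticulum unfolded protein response list was inside its random range at 0.31, with HYOU1 at 0.38, and p53 targets were inside at 0.35, with CDKN1A, a cell cycle inhibitor, at 0.70. Medians of the other lists inside their range were 0.30 for translation factors of TOP mRNAs, 0.21 for mRNAs with regulatory upstream frames, -0.05 for cell cycle genes (-0.59 and outside with the stop window alone), -0.09 for NRF2 targets, -0.11 for the respiratory chain, -0.12 for aminoacyl-tRNA synthetases, -0.22 for lysosome and autophagy and -0.44 for glycolysis. The interferon list had 2 members, IFITM1 at 0.62 and IRF1 at 0.50.

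By size of change, the highest named mRNAs were ERFE, a hormone of iron metabolism, at 2.2 (1.99 to 2.73), HHAT at 1.87, the deubiquitinase USP7 at 1.84, BHLHE40 at 1.61, OLR1 at 1.58 and INAFM1 at 1.51. They were followed by DDB2, a p53 target of DNA repair, at 1.36, HMGB2, CLDN1 and AGO4. The lowest were the splicing factor SRSF6 at -1.78 (-1.92 to -1.66), NDUFC2 of respiratory complex I at -1.78, HSPA1B, ATP6V0C, CHCHD10, UBP1, TMEM41A, RPL22L1, TKFC and, at -1.42, the proteasome subunit PSMD1. In total 211 transcripts were at least 2-fold higher and 161 lower among 9423, with a median log2 ratio of -0.004. The balance turned with the start window alone, 447 higher and 739 lower, and with the stop window alone, 542 and 788, and was even at a threshold of 1.5, 900 and 903. In the authors' deposited fold values for 2118 coding frames, 5 were at least 2-fold higher and 28 lower. With reads of the window around the stop codon alone USP7 was at -0.18 and IFITM1 at -0.064, and with the start window alone KLF4 was at 0.38.

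**Figure D1:**
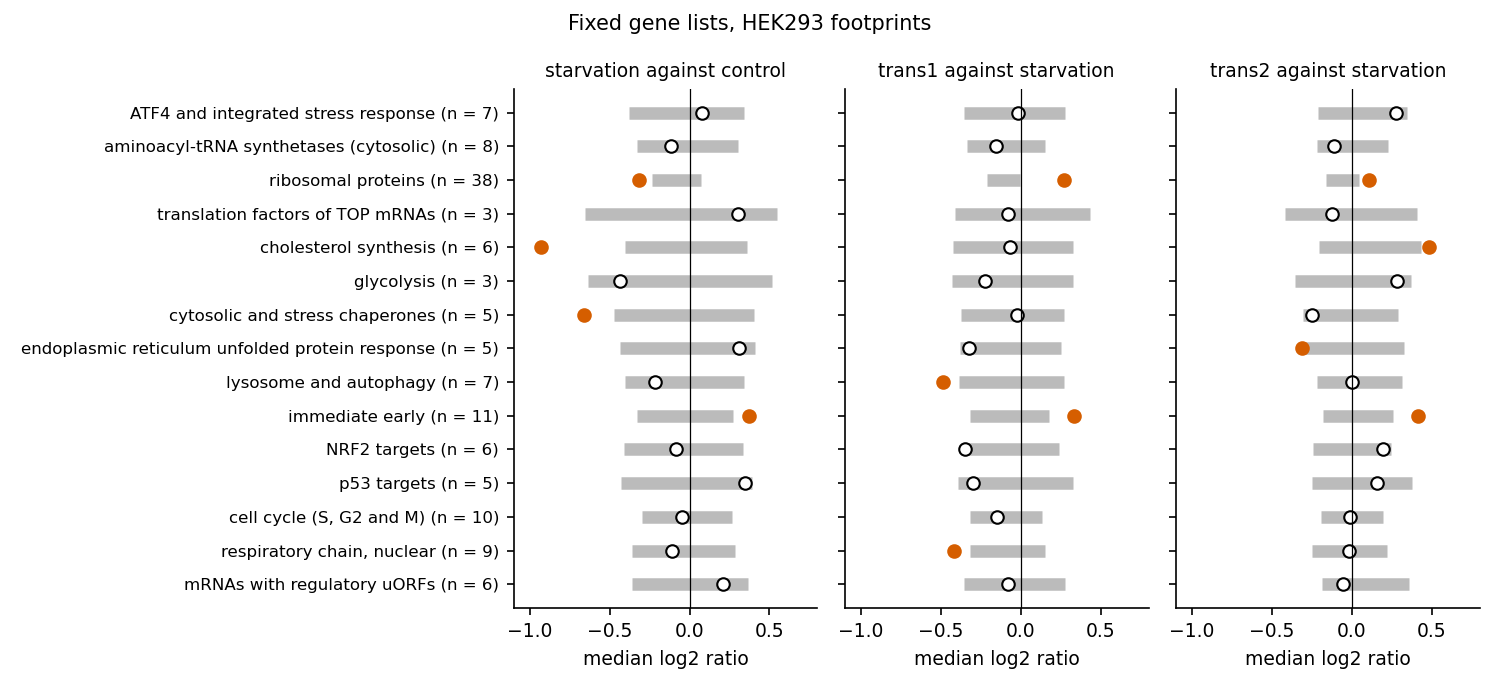
Median log2 ratio of each fixed gene list (point) in the 3 footprint comparisons, with the central 95% of 10000 matched random lists (grey bar) and the number of measured members in brackets. Filled points lie outside that range, as for cholesterol synthesis at -0.93 under starvation and ribosomal proteins at 0.27 in trans1.

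The next comparisons ask what the trans-RNA adds to starvation. No starvation library with a control RNA is among the groups, so an effect of transfection itself cannot be told apart here. The starvation library enters these ratios with opposite sign to the first, so a list that turns back is partly built in. How much of such a turn comes from that library is not known. In trans1, ribosomal protein mRNAs carried more footprints than under starvation alone, and mRNAs of the respiratory chain and of lysosomes carried fewer. Of 38 ribosomal protein mRNAs 32 were above 0, with a median of 0.27 above every random list, and RPLP1 was at 0.84, RPLP2 at 0.77 and RPL41 at 0.76. All 9 respiratory chain mRNAs were lower, with a median of -0.42 at percentile 0.105. ATP5F1A of the ATP synthase, NDUFV1 of complex I and SDHB of complex II were each at -0.58. With the stop window alone that list was inside its range at -0.26. All 7 lysosome and autophagy mRNAs were lower, with a median of -0.49 at percentile 0.355, including MAP1LC3B at -0.65, the protease CTSB at -0.63 and BECN1 at -0.49. That list was inside its range with the start window alone, at -0.55, and with the stop window alone, at -0.26.

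Immediate early mRNAs were higher in trans1 as well, with a median of 0.33 at percentile 99.9, led by JUNB at 1.24, FOSL1 at 1.06 and JUN at 0.88, while KLF6 was at -0.61. With the start window alone that median was 0.18, inside its range. The ATF4 and integrated stress response list was inside its random range at -0.02, with ALDH18A1 at -0.66. All 6 NRF2 targets were lower, yet their median of -0.35 stayed inside the range, with FTH1, the ferritin heavy chain, at -0.58 and GCLC of glutathione synthesis at -0.51. The unfolded protein response list was inside at -0.32, with HYOU1 at -0.62 and HERPUD1 at -0.55. The other medians inside their range were -0.02 for chaperones, -0.07 for cholesterol synthesis (-0.81 and outside with the start window alone), -0.08 for translation factors of TOP mRNAs, -0.08 for mRNAs with regulatory upstream frames, -0.15 for cell cycle genes, -0.16 for aminoacyl-tRNA synthetases, -0.22 for glycolysis and -0.30 for p53 targets. Of the interferon list, IRF1 was at 0.64 and IFITM1 at -0.46.

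The highest named mRNAs in trans1 were SLC2A13 at 2.01, TBC1D17 at 1.5, RIBC2 at 1.28, JUNB, ZNF184, TRMT44, the homeobox gene DLX1, COL18A1, TIGD7 and SIX4, the last at 1.09. For SLC2A13, 97.1% of the reads in the windows lay at 1 position. The lowest were the dopamine transporter SLC6A3 at -1.72 (-2.87 to -1.29), ARL16, GNG7, BPNT1, RECK, ILVBL, WRAP53, the small GTPase CDC42, USP20 and TPCN2, the last at -1.03. In total 100 transcripts were at least 2-fold higher and 94 lower among 9411, a share of 51.5% higher, with a median of -0.08. Centring on that median gave 135 higher and 63 lower, a share of 68.2%, and reads at 8 or more positions gave 55 and 28. More were lower with the start window alone, 435 and 719, with the stop window alone, 420 and 904, without the highest position of each transcript, 104 and 125, with a pseudocount of 0.1, 135 and 146, and at a threshold of 1.5, 518 and 709, so the balance depends on the setting. The authors' coding frames gave 0 higher and 35 lower. With the stop window alone TBC1D17 was at -1.78 and IRF1 at -0.0696, and with the start window alone JUN was at -0.085.

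In trans2, immediate early and cholesterol mRNAs were higher than under starvation alone. All 11 immediate early mRNAs were above 0, with a median of 0.41 at percentile 99.8, and KLF4 was at 1.06, JUNB at 0.87, DUSP1 at 0.82 and JUN at 0.80. Of 6 cholesterol mRNAs 5 were higher, with a median of 0.48 at percentile 98.7, including SQLE at 0.63, DHCR7 at 0.49 and HSD17B7 at 0.47, but that list was inside its range with the start window alone, at 0.59, and with the stop window alone, at 0.43. Ribosomal protein mRNAs had a median of 0.11 at percentile 99.9, with 26 of 38 above 0, RPL37A at 0.65 and RPS19 at 0.47, and lay inside the range of random lists without matching. All 5 unfolded protein response mRNAs were lower, with a median of -0.31 at percentile 2.4, including the chaperone CANX at -0.34 and HYOU1 at -0.28. That list was inside its range at -0.28 with a pseudocount of 5 and at -0.16 with the start window alone. Centring put it at -0.35, also inside, but shifts the random lists alike. That change of place comes from new random draws alone and shows how near the edge the list lies.

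The ATF4 and integrated stress response list had a median of 0.27 in trans2, inside its random range at percentile 94.3, and the stop window alone put it at -0.19. The amino acid transporters SLC7A1 at 0.53 (0.30 to 0.79) and SLC7A5 at 0.40 (0.30 to 0.49) and the stress sensor SESN2 at 0.57 were its highest members. NRF2 targets were inside at 0.20, with FTH1 at 0.88 and GCLC at 0.62. The other medians inside their range were 0.28 for glycolysis, 0.16 for p53 targets, 0.003 for lysosome and autophagy, -0.01 for cell cycle genes, -0.02 for the respiratory chain, -0.05 for mRNAs with regulatory upstream frames, -0.11 for aminoacyl-tRNA synthetases, -0.13 for translation factors of TOP mRNAs and -0.25 for chaperones. RARS1, a synthetase at 1.42, had 87.2% of its window reads at 1 position. Of the interferon list, IRF1 was at 0.70 and IFITM1 at -0.05.

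The highest named mRNAs in trans2 were SOX4 at 2.88, ATG101 at 2.26, KIF9 at 2.10, KCTD19 at 1.96, RCHY1 at 1.70, MRPL22, C4orf19, ASB1, the homeobox gene DLX3 and CDC34, the last at 1.47. The share of window reads at 1 position was 99.1% for SOX4, 86.5% for ATG101, 91.8% for KIF9 and 55.9% for KCTD19. The lowest were CDC42 at -1.04 (-1.28 to -0.84), GFPT2 at -0.90, the nuclear pore protein TPR at -0.89, MAP3K15, ZFX, SREK1IP1, PJA2, MFSD14A, RECK and TTBK2, the last at -0.71. In total 143 transcripts were at least 2-fold higher and 14 lower among 9423, with a median of 0.04. The authors' coding frames gave 0 higher and 3 lower. In the stop window alone RCHY1 was at -0.55, MRPL22 at -0.052, SESN2 at -0.39, CDC42 at 0.44, TPR at 0.40, PJA2 at 0.49 and TTBK2 at 0.67, and in the start window alone ATG101 was at -0.055, RCHY1 at -0.49 and GCLC at -0.15.

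Some transcripts rose in both trans-RNA libraries. A set of 29 was at least 2-fold higher in both and 4 were lower in both. Independent draws of the observed numbers give 1.51 and 0.14, but leave out the shared starvation library. Simulations of counting noise around that library gave at most 2 and 1, but call a mean of only 0.31 transcripts higher in trans1, so neither value is a full measure of no sharing. The shared gains with a symbol were HOXB8, SPNS1, SYCE1L, IFT140, KHNYN, CAMK1D and KIF9, and 22 had none. Over 9410 transcripts 54.8% moved in the same direction, below the 62.4% to 65.2% of these 200 simulations, while the covariance of 0.0345 was above the simulated 0.00885. The starvation library enters both ratios and cannot be split, so how much of that excess comes from it is not known.

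The largest gain in trans1 was on ENST00000674920, for which the tables give no symbol. Whether this transcript belongs to ATF4, the target, could not be looked up here. It had 295 CPM in control, 498 in starvation, 8115 in trans1 and 4725 in trans2, log2 ratios of 4.02 (3.98 to 4.07) and 3.24 (3.20 to 3.29) over starvation. Footprints at positions in the 30 nt before its start codon were 50.4-fold higher in trans1 and 17.7-fold higher in trans2. With the offset not known, these may include ribosomes on the start codon. Footprints placed in the first 100 nt of its coding region were 41.8-fold and 27.7-fold higher. Over the next 100 nt they were 3.99-fold and 3.47-fold higher. From nt 200 to 300 the folds were 0.722 and 1.08, and over the last 300 nt of the coding region 0.899 and 0.634. Reads of the transcript outside these windows, which cannot be placed, were 13.7-fold and 9.54-fold higher. Starvation alone changed the start window 1.29-fold and the last 300 nt 4.08-fold against control. Among 3611 transcripts in trans1 and 4047 in trans2, it ranked 1 for the difference between start and stop windows.

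**Figure D2:**
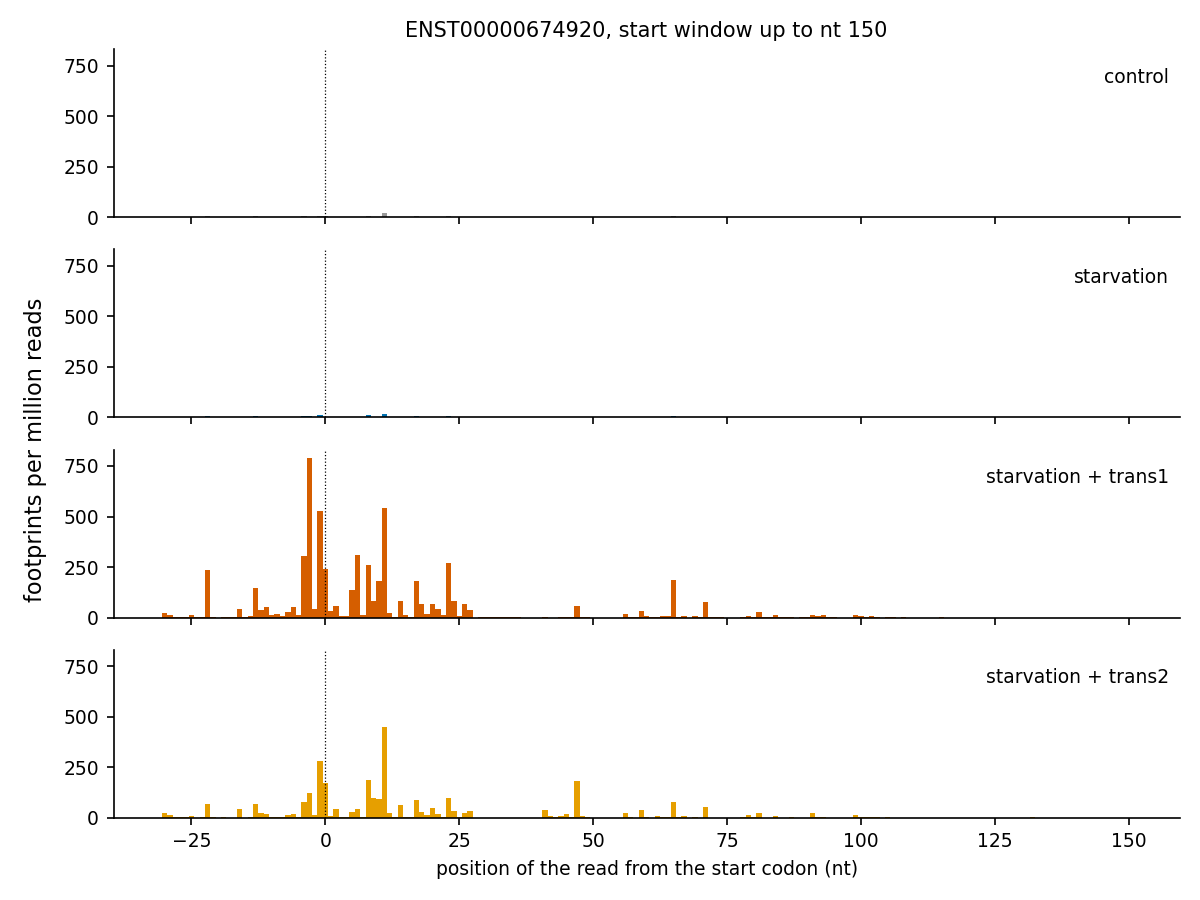
CPM at each position around the start codon (dotted line) of ENST00000674920 in the 4 HEK293 libraries, on a common axis. In trans1 and trans2 the gain within this window sits around the start codon, with the highest position at -3 in trans1 and at 11 in trans2.

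Across all transcripts the footprint profile had its highest positions at the same places in the 4 libraries, but trans1 was higher at position -3. The highest mean density before the start codon lay at position -12 in each, with 7.70 in control, 8.75 in starvation, 7.95 in trans1 and 8.17 in trans2, relative to a transcript mean of about 1. Before the stop codon it lay at -18, with 10.95, 11.8, 10.5 and 10.1 in the same order. At position -3, trans1 was at 5.13 (4.35 to 5.89 over draws of transcripts) against 3.15 (2.83 to 3.54) in control, 3.62 (3.13 to 4.14) in starvation and 3.31 (2.92 to 3.76) in trans2. The share of window density at positions before the start codon was 8.96% in control, 9.07% in starvation, 9.20% in trans1 and 8.95% in trans2. An even spread gives 9.06%. That share takes in the peak at -12 and, with the offset not known, may count ribosomes on the start codon. Frame 0 held 86.3%, 87.4%, 85.2% and 84.3% of coding footprints.

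The authors' lists of translated frames held 5499 frames in control, 4207 in starvation, 2866 in trans1 and 4258 in trans2, all under mouse gene IDs, so no gene of HEK293 could be named in them. Truncated coding frames were the main class, with 53.2%, 53.4%, 51.2% and 56.1%, while complete coding frames were 152, 106, 34 and 137. These are 19.3, 21.2, 43.2 and 17.4 truncated frames per complete one, against 4.45 in the authors' fold tables under human IDs. The cause of that gap was not tested, so the excess of truncated frames is not read as a property of the cells. Upstream frames that end before the coding region made up 3.33% (2.87 to 3.84) in control, 3.33% in starvation, 3.04% in trans1 and 3.55% in trans2. Frames that overlap the start of the coding region numbered 49, 28, 21 and 41, frames on noncoding RNAs 1268, 955, 684 and 918. Reads of upstream and overlapping frames together were also set against those of complete coding frames, in genes with both. They took 5.51% of the reads of these frames in control, 13.4% in starvation, 34.3% in trans1 and 22.3% in trans2. These shares come from 14, 17, 2 and 14 genes and leave out truncated coding frames, so they are not shares of all reads of a gene. The medians over these genes were 11.98%, 10.7%, 33.1% and 16.8%, so the rise from control to starvation holds for pooled reads alone. A single gene took 81.0%, 62.2%, 89.0% and 79.9% of all assigned reads. In the same order, frames on noncoding RNAs held about 6005170, 1800720, 4798170 and 3178410 of about 7060320, 2589370, 5256700 and 3783670 reads. Most reads of that gene thus lay on noncoding frames in each library. Any 2 lists shared 19.5% to 31.4% of the frames of the smaller list, or 65.0% to 73.7% when matched by gene and end.

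The authors' fold values are given per frame under human transcript IDs, 41748 in each comparison, and their medians were -0.08 for starvation, -0.39 for trans1 and -0.19 for trans2. Frames overlapping the start of the coding region had the highest value in both trans-RNA comparisons, at 5.31 on ENST00000675582 and ENST00000679776 in trans1 and 4.39 on ENST00000679776 in trans2. That class as a whole had a median of -0.46 in trans1 and -0.19 in trans2, near those of all frames. At 2-fold 8 of its 1581 frames were higher and 151 lower in trans1, and 11 and 54 in trans2. Over all 41748 frames these counts were 295 and 3171 in trans1 and 299 and 1792 in trans2. A 16-fold gain was passed by 14 frames on 8 transcripts in trans1, by 12 on 7 in trans2 and by 0 under starvation. Among 2118 complete coding frames the highest was 0.48 in trans1 and 0.86 in trans2.

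The small RNA libraries ask where capped small RNAs lie on mRNAs, compared with all small RNAs. Capped RNAs on the sense strand lay mainly in 5′ untranslated regions, with 61.7% (60.3 to 63.2) of 4521 peaks against 12.8% (11.7 to 14.0) of 3416 in the total library. On the antisense strand the shares were alike, 13.3% of 1810 peaks in the cap and 12.8% of 2424 in the total library. Sense peaks made up 71.4% of the cap list and 58.5% of the total list. Capped sense peaks within 15 nt of a start codon were 6.88% against 1.90%, and the median 5′ distance was -137 nt against -331 nt. The lists' counts sum to 637679 sense and 78796 antisense reads for cap, and to 536974 and 119784 for total. The depth of the whole libraries was not used here.

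By gene group, 1975 of 5745 genes with any peak had a capped sense peak in the 5′ untranslated region, or 34.4% (33.1 to 35.6). The counts below are also out of list members with any peak. A gene can thus enter through the counted peak alone, and expression was not matched. The immediate early list had one in 12 of 17 genes, or 70.6% (44.0 to 89.7), including IER2 with 726 reads at -132 and IER5 with 52. p53 targets had one in 6 of 7, with CDKN1A at 30 reads, and unfolded protein response genes in 6 of 8. Ribosomal proteins had one in 26 of 61, with RPLP1 at 60 reads, glycolysis genes in 7 of 10, aminoacyl-tRNA synthetases in 7 of 10 and lysosome genes in 5 of 8. The ATF4 and integrated stress response list had one in 4 of 11, with SESN2 at 39 reads and SLC7A5 at 34, and ATF4 had 0 peaks in any list. Counts were 2 of 8 for cholesterol synthesis, 2 of 9 for interferon genes, 1 of 8 for translation factors of TOP mRNAs, 4 of 8 for chaperones, 4 of 7 for NRF2 targets, 9 of 18 for cell cycle genes, 7 of 15 for the respiratory chain and 5 of 10 for mRNAs with regulatory upstream frames. The ferritin light chain FTL had 2574 reads at -199, and SAT1, a polyamine enzyme, 120.

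**Figure D3:**
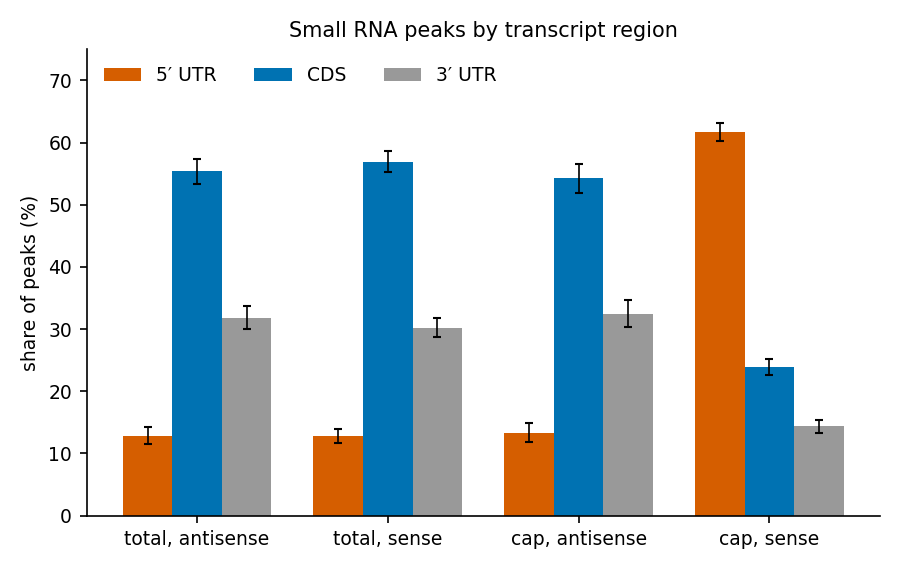
Share of small RNA peaks in each transcript region, per library and strand, with exact 95% intervals of counting error. The 5′ untranslated region holds 61.7% of capped sense peaks and 12.8% to 13.3% in the other 3 lists.

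Sharing of sites depends on the list it is counted from. Of capped sense peaks in 5′ untranslated regions, 9.39% lay within 10 nt of a peak of the total library, against 48.4% in coding regions and 61.5% in 3′ untranslated regions. Of total sense peaks, which are far fewer in 5′ untranslated regions, 60.7% there lay near a capped peak, against 27.0% and 46.3%. Of capped antisense peaks 59.3% were shared with the total library. Antisense and sense peaks met at the same place for 2.48% of antisense peaks in the total list and 3.59% in the cap list. The highest sense peaks were on CTC1, a telomere maintenance gene, with 162006 reads in the total library, and on TMEM107 with 104160, TUT1 with 68849 and WDR74 with 62696 in the cap library. The highest named antisense peaks were on HCFC1 with 8085 reads in the total list, and on CDAN1 with 6206 and the kinase MTOR with 4320 in the cap list.

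In mouse liver, the first comparison asks what fasting changes. Of 10200 transcripts, 445 were at least 2-fold higher after fasting and 1070 lower, where counting noise alone gives about 9.95 and 10.6. The median log2 ratio was -0.28, and centring on it gave 831 higher and 494 lower, a share of 62.7% higher against 29.4% as deposited. The deposited files do not pair these transcripts with gene symbols. The highest were ENSMUST00000020308 at 5.03 and ENSMUST00000034585, from 19.1 to 477 RPKM, at 4.58 (4.50 to 4.79). The lowest were ENSMUST00000029046 at -5.15 and ENSMUST00000044094, from 74.4 to 1.13 RPKM, at -5.14.

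The trans-RNA comparison in fasted liver gave 456 transcripts at least 2-fold higher and 119 lower among 10017. No fasted liver with a control RNA is among the groups, so an effect of delivering RNA cannot be told apart here. The median was 0.18, and centring gave 262 higher and 215 lower, a share of 54.9% higher against 79.3% as deposited. The transcripts lowest after fasting were the highest here, with ENSMUST00000044094 at 4.40 and ENSMUST00000029046 at 4.17. The lowest were ENSMUST00000034215 at -2.22 and ENSMUST00000034585 at -2.07 (-2.14 to -2.02).

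Most fasting changes were smaller in the trans-RNA library. Of 1354 changed transcripts measured in both comparisons, 1267 moved back towards the fed level, or 93.6% (92.1 to 94.8). This leaves out lowered transcripts below 1 RPKM in both fasting libraries. Filtered on fed and fasting alone, 1387 of 1515 moved back, or 91.6% (90.0 to 92.9), and 993 of 1070 lowered ones, or 92.8%. Of the transcripts higher after fasting 394 of 445 moved back, or 88.5%, against 35.4% (random draws, 31.2 to 39.6) of other transcripts of like expression, and of those lower 873 of 909, or 96.0%, against 62.1% (random draws, 59.3 to 65.1). Relative to fed liver, 178 of the higher and 127 of the lower stayed at least 2-fold changed, or 211 of the lower when filtered on fed and fasting alone. The fasting library enters both ratios, and counting noise alone sends back 88.5% of a mean of 16.9 transcripts. With the fasting change kept and trans1 unchanged, simulations gave 59.5%.

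**Figure D4:**
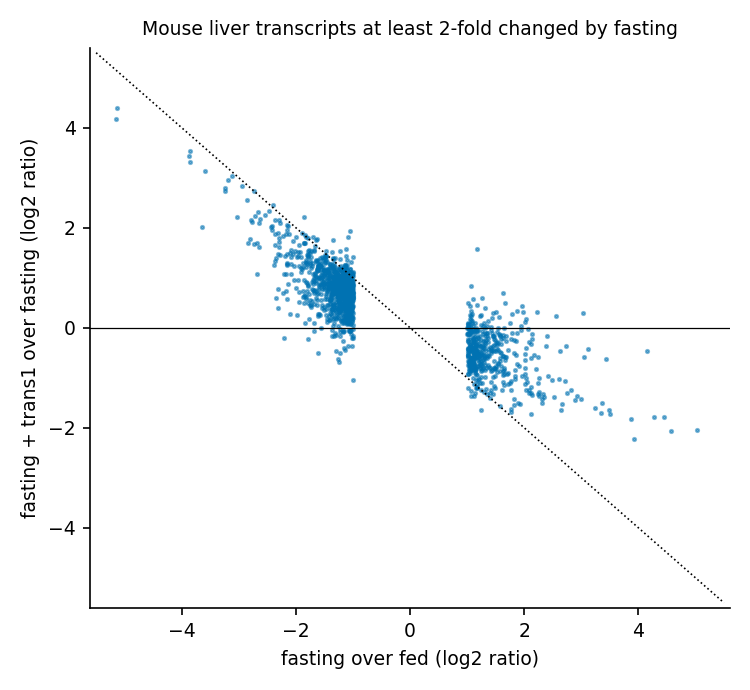
Each point is 1 of 1354 mouse liver transcripts at least 2-fold changed by fasting, with its log2 ratio of fasting over fed against that of fasting with trans1 over fasting. Points on the dotted line return to the fed level, and 1267 lie on the side of 0 that leads towards it.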

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

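Under alternatives fixed beforehand none of 236 values of single genes changed sign. This says little, since a changed pseudocount cannot turn a sign and centring only subtracts the median. Of single genes, the start window alone turned 6 of 116 and the stop window alone 14 of 109. Of 360 list medians, fixed and added alternatives together, 347 kept their place inside or outside the random range. Centring turned the sign of 6 medians that were within 0.0816 of 0 and stayed inside it. It shifts each list and its random lists alike, so under centring the places of 45 medians could change by new random draws alone. Reads of the start window alone turned 11 medians and those of the stop window alone 9, none of which crossed the edge of the range. No replicate exists, so none could be left out. Start or stop window alone, at least 8 positions, removal of the highest position, liver CPM, at least 50 liver reads and the filter on fed and fasting alone were chosen after the results were seen. Counts of 2-fold changes moved most, 61 of 98 by more than 1.5-fold, since a larger pseudocount and a higher filter act on transcripts with few reads, and a lower threshold admits smaller changes. For other settings the cause was not tested.

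A pseudocount of 0.1 gave 146 lower in trans1 and 24 lower in trans2, and in liver 877 higher and 2088 lower for fasting, 1237 higher and 347 lower for trans1. A pseudocount of 5 gave 108 higher and 79 lower for starvation, 29 and 14 for trans1, 58 and 2 for trans2, 143 and 253 for liver fasting, 84 and 28 for liver trans1, and -0.28 for the unfolded protein response in trans2, now inside its range. A filter at 10 gave 57 lower in trans1 and 8 lower in trans2, and in liver 174 and 372 for fasting, 148 and 44 for trans1, with 95.3% moving back towards fed. A threshold of 1.5 gave 900 and 903 for starvation, 518 and 709 for trans1, 759 and 177 for trans2, 1106 and 2936 for liver fasting, 1838 and 531 for liver trans1, with 88.8% moving back. Centring gave 831 and 494 for liver fasting and 262 and 215 for liver trans1. The unfolded protein response in trans2 was then at -0.35 and inside its range, a change of place from new random draws alone. Random lists without matching put ribosomal proteins in trans2, still at 0.11, inside the range.

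The authors' fold values for coding frames gave 5 higher and 28 lower for starvation, 0 and 35 for trans1, and 0 and 3 for trans2; the frames differ from the transcripts and the cause was not tested. Reads at 8 or more positions gave 55 and 28 for trans1 and 9 lower for trans2. A filter on fed and fasting alone, which keeps lowered transcripts that stayed below 1 RPKM, gave 91.6% moving back. Liver CPM gave 814 and 1849 for fasting and 1043 and 272 for trans1.

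The start window alone, with fewer reads, gave 447 and 739 for starvation, 435 and 719 for trans1 and 745 and 169 for trans2. The stop window alone gave 542 and 788, 420 and 904, and 793 and 241. In the start window, list medians were -0.81 for cholesterol synthesis in trans1, now outside its range, -0.55 for lysosome and autophagy in trans1, 0.18 for immediate early genes in trans1, 0.59 for cholesterol synthesis in trans2 and -0.16 for the unfolded protein response in trans2, these 4 now inside. In the stop window they were -0.59 for cell cycle genes under starvation, now outside, 0.25 for immediate early genes under starvation, -0.26 for lysosome and autophagy and -0.26 for the respiratory chain in trans1, and 0.43 for cholesterol synthesis in trans2, these 4 now inside.

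Single genes were run under centring, a pseudocount of 0.1 and each window alone, and signs turned in the windows. In the start window KLF4 was at 0.38 under starvation, JUN at -0.085 in trans1, and in trans2 ATG101 at -0.055, RCHY1 at -0.49 and GCLC at -0.15. In the stop window USP7 was at -0.18 and IFITM1 at -0.064 under starvation, TBC1D17 at -1.78 and IRF1 at -0.0696 in trans1, and in trans2 RCHY1 at -0.55, MRPL22 at -0.052, CDC42 at 0.44, TPR at 0.40, PJA2 at 0.49, TTBK2 at 0.67 and SESN2 at -0.39. ENST00000674920 was at -0.13 in trans1 and -0.54 in trans2 there, since its gain lies outside the last 300 nt.

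Of the mean densities, medians over transcripts were 0 at each position and in each library, since at least 1 in 2 transcripts has no read there. A trimmed mean gave, in the order control, starvation, trans1 and trans2, 4.78, 4.80, 4.02 and 4.79 at -12, 1.67, 1.69, 2.26 and 1.66 at -3, and 8.18, 7.46, 6.93 and 6.83 at -18 from the stop codon. Transcripts present in all 4 libraries gave 12.2 at -18 in control. The upstream share of summed density was 9.59% in starvation and 9.67% in trans1.

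Frames with at least 10 reads left 92 upstream frames in starvation, 51 in trans1 and 100 in trans2. A p of at most 0.01 left, in the same order of 4 libraries, 48, 27, 13 and 38 upstream frames, 14, 6, 7 and 15 overlapping frames, and 500, 350, 229 and 356 noncoding frames. Matching frames by gene and end gave shared numbers of 2928, 1893 and 3040 for control with starvation, trans1 and trans2, 1945 and 2734 for starvation with trans1 and trans2, and 1806 for trans1 with trans2. Peaks of at least 8 reads numbered 1283 antisense and 1608 sense in the total list and 946 and 1953 in the cap list. With 1 peak per transcript 54.6% of total peaks were sense.

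In trans1 1617 of the transcripts kept have reads at fewer than 8 positions, against 186 in control. A step found from so few positions can stand for several reads, which lowers the reads of that library alone. Fewer than 8 positions in trans1 or starvation were found for 45 of the 100 transcripts higher in trans1 and 66 of the 94 lower. Of 200 simulated 3-fold changes 196 were called at the depth of trans1 and 197 for starvation. These counts were drawn from recovered reads, so they do not test that step. ATF4 has no value by name under any setting.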

Other observations

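Tests of the transcript with the largest gain, of small RNA genes near the highest peaks, of counting noise in the liver and of the fasting library were chosen after the results were seen, and those of abundant mRNAs and of a blended library before.

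Seen against control rather than starvation, the trans-RNA libraries lay on the side of the starvation library for some lists and not for others. The starvation ratio and both of these ratios share the 1 control library. Agreement between them is thus partly built in, and a control library that stands apart would give it too. Cholesterol mRNAs were lower than in control, with 6 of 6 below 0 in both and medians of -1.0 in trans1 and -0.52 in trans2. So were chaperones, 5 of 5 in both, at -0.68 and -0.91. Immediate early genes were further above control, at 0.59 and 0.67, with 7 of 11 above 0 in trans1 and 11 of 11 in trans2. Ribosomal proteins were at -0.04 in trans1, inside their random range at percentile 88.4, and at -0.22 in trans2, just inside at percentile 2.75, with 30 of 38 below 0. The respiratory chain was at -0.68 in trans1, with 9 of 9 below 0, and at -0.12 in trans2, and p53 targets were at 0.40 in trans1, inside their range at percentile 93.6 with 3 of 5 above 0, and at 0.86 in trans2, above 99.9% of random lists. Over 5810 well covered transcripts, trans1 and trans2 differed from each other by a robust spread of 0.408, more than either differed from starvation, 0.305 and 0.278.

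In liver, a few transcripts made up much of the RNA in each state. The 10 highest took 34.3% of summed RPKM in fed, 39.1% in fasting and 36.1% in the trans-RNA library, and 9 of the 10 highest in fed liver were among the 10 highest in the other libraries. The number of transcripts at 10 RPKM or more was 2270 in fed, 1886 in fasting and 2153 with the trans-RNA.

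Footprints near the start codon of ENST00000674920 were far higher in both trans-RNA libraries. A pile of reads at 1 position does not account for it. Without the highest position the gain was still 18.6-fold in trans2 and 34.7-fold in trans1. An even gain along the whole coding region does not account for it either, since the higher fold at nt 200 to 300 was 1.08. Reads outside the windows, which cannot be placed, were 13.7-fold higher in trans1 and 9.54-fold in trans2. A further gain elsewhere in the coding region thus stays open. Fragments without a reading frame, such as pieces of the added RNA, cannot be told apart, since the leading frame held 54.8% (38.7 to 70.2) of triplets in trans1 and 55.8% in trans2, where 3 even frames give 41.0% and 40.9%, inside these intervals, and pieces with fixed ends need not be even. Ribosomes on an upstream frame that runs into the coding region may be a source as well. The gain at nt -30 to -16 was at least 26.2-fold in both. It is part of the upstream gain already seen, so it gives no separate support. The leading frame by triplets was the same in control and starvation. From nt 30 to 299 it held most reads in trans1, 64.8%, and trans2, 65.2%, and the largest share in control, 46.3%, while frame 0 led in starvation, 59.9%, and a biological effect of the trans-RNA itself was not tested apart from this.

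The highest sense peaks of the small RNA lists lie on genes that host or adjoin small RNA genes in some cases, such as TMEM107 with SNORD118, WDR74 with RNU2-2 and CTC1 with 3 tRNA genes. A small RNA gene lay inside or within 1 kb for 18.75% of the 16 cap genes with a peak of at least 1000, where length-matched genes gave 0% to 25.0%, and for 33.3% of 15 total genes, where they gave 0% to 33.3%, so the number of genes is too small to decide. Pieces of abundant translated mRNAs cannot be told apart either, because footprints were measured for 46.7% and 37.5% of these genes only, with a median rank at percentile 71.8 in the total list. No biological explanation was tested.

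Most fasting-changed liver transcripts returned towards the fed level in the trans-RNA library. Counting noise in the shared fasting library does not account for it, since the covariance of both ratios was -0.252 and the lowest of 200 simulations was -0.0220. A library blended from fed and fasting RNA stays open: 2.72% of 5252 transcripts lay at least 1.5-fold outside both levels, but simulated blends, at most 0.0190%, carry counting noise alone and no difference between preparations. A fasting library that stands apart for a reason of its own cannot be told apart from an effect of the trans-RNA, since 1 library was made per state and the robust spread from fed was 0.332 for the trans-RNA library and 0.564 for fasting. An effect of the trans-RNA in liver, or of delivering any RNA, may thus be one of the open explanations, as a hypothesis from these same data.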
